A study of Homo sapiens with 28 samples.

How the data were processed

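RNA of 28 samples of 3 established neuroblastoma cell lines in 11 groups was measured, 1 Affymetrix 3' array per sample. Per the labels' protocols, cells were grown in RPMI 1640 with fetal bovine serum, counted, and lysed in Trizol, and ERCC ExFold control RNA was added in proportion to cell number. From 100 ng of total RNA, labelled RNA was made with the 3' IVT Express kit. Per the labels, the authors computed 1 intensity per probe set and array with MAS5 (version not stated). The deposited values are on a linear scale, and the 40 bright ERCC probe sets sit at about the same level on every array, which points to a further scaling by a method not given in the sources used here. The median of all 100 varied more (5.23 to 5.66 on the log2 scale). Doses, times, lines and groups were taken from the labels, and the groups hold 2 or 3 arrays.

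The table holds 49495 probe sets, of which 100 are ERCC, 23 are background and 79 are other controls. By the array annotation 45278 probe sets have 1 gene, 1333 have several and 2682 have none, and only the first kind was used. Symbols were updated through Entrez identifiers with the gene annotation of the GRCh38.p14 assembly (45214 probe sets) or kept (70), and no coordinates were used. Values were used as log2 of the intensity plus 1. Each of 18244 genes was represented by its brightest probe set over all arrays, which left 8811 of the tested genes with further probe sets. The 11666 genes with a mean intensity of 100 or more in at least 1 group were tested (63.9% of the genes, as 54.7% of probe sets). Signal over background limits precision: a gene within 1 log2 unit of the mean background of its group was called near the background.

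All 11 groups were fitted together by limma 3.58.1 under R 4.3.3 with 1 mean per group and moderated variances, and 13 comparisons were tested, 10 of 2 groups and 3 of differences between THZ1 effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. The overall change per comparison was the median over genes of the difference of each array from the control mean, tested by exact permutation of the arrays. Named were MYCN, MYC and CDK7, in each comparison the 6 largest rises and falls among called genes with no overlap of the groups (for differences of effects, among called genes), and for each list up to 4 called members with the largest changes, or the 2 brightest if none was called. From these sets some members were left out, 1 of them under the rule on human samples. The 21 gene lists were written by hand from general knowledge: MYC family and partners, noradrenergic core transcription factors, noradrenergic and neuronal differentiation markers, mesenchymal markers, ribosome biogenesis, growth and metabolism genes known as MYC targets, immediate early genes, RNA polymerase II machinery, mitosis, S phase, DNA repair, apoptosis, p53 targets, stress response, interferon response, cholesterol synthesis, histones, cytosolic ribosomal proteins, oxidative phosphorylation, and markers of immune and endothelial and of Schwann and glial cells. Of their 493 genes 453 had a probe set of their own and 40 had none. Lists were tested by limma's camera with the preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the 21 lists, and called by the first. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

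Groups, comparisons, tests, lists, the naming rule and the first set of alternatives were chosen before the data were examined. These alternatives were: setting array medians equal, setting the median ERCC probe set equal, no filter on level, a pseudocount of 32, the mean of all probe sets of a gene, a fit on the compared groups alone, replicate numbers as blocks, a 2-fold threshold, an estimated list correlation, and leaving out each array. Scaling to the 40 bright ERCC probe sets, equal median differences of the arrays from their mean (for the list tests too), lists of matched brightness, and averaged probe sets for genes shared by the THZ1 comparisons were added after the data were seen. The code was tested on simulated data with the variances of the 11666 genes, 200 of them changed. At log2 changes of 0.5, 1 and 2 it recovered 44.8%, 98.5% and 100% in Kelly with THZ1, 35.8%, 97.0% and 100% in IMR-32, 49.3%, 94.0% and 100% in SH-SY5Y, and 26.9%, 88.1% and 100% in SH-SY5Y with MYCN. It recovered 35.8%, 95.5% and 100% for actinomycin D, 29.9%, 91.0% and 100% for THZ1 against it, 20.9%, 95.5% and 100% for shMYCN, and 31.3%, 97.0% and 100% for MYCN in SH-SY5Y. Between lines it recovered 29.9%, 97.0% and 100% (Kelly) and 47.8%, 100% and 100% (IMR-32). For the differences of effects it recovered 5.97%, 73.1% and 100% (Kelly), 16.4%, 80.6% and 100% (IMR-32) and 7.46%, 58.2% and 100% (SH-SY5Y with MYCN). With 200 changed genes, small differences between effects were thus mostly missed. The adjusted threshold is less strict where most genes are called, so these shares do not give the sensitivity in such comparisons. All 3 list tests called 1 list shifted by 0.5 in simulated data and none of the other 20. The simulated genes varied independently, with no shift of whole arrays, so this does not show which test holds where the 3 disagree.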

Results

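RNA levels were measured on 28 Affymetrix 3' expression arrays in 3 lines of neuroblastoma, a childhood cancer of the sympathetic nervous system. Kelly and IMR-32 are labelled high in MYCN, a transcription factor of the MYC family that is amplified in some neuroblastomas, and SH-SY5Y is labelled low. THZ1 is a covalent inhibitor of CDK7, a kinase that phosphorylates RNA polymerase II and activates the kinases of the cell cycle. It was given at 100 nM for 6 h, with its solvent DMSO as the control, to Kelly, IMR-32 and SH-SY5Y (3 arrays each with THZ1 and 3 with DMSO). Kelly was also treated with actinomycin D, a DNA-binding compound that stops RNA synthesis, at 1 µM for 6 h (2 arrays). Kelly with a short hairpin RNA against MYCN (shMYCN) or against the foreign gene GFP (shGFP) gave 2 arrays each, and SH-SY5Y overexpressing MYCN gave 2 arrays with THZ1 and 2 without. By its title, the study addressed transcription driven by super-enhancers, large clusters of enhancers, in cells that depend on MYCN, and what CDK7 inhibition does to it. Of 18244 genes with a probe set of their own, 11666 reached a mean intensity of 100 in at least 1 group and were tested.

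The median intensity of the tested genes per array was 191 to 230 in Kelly with DMSO, 89.1 to 97.4 with THZ1 and 80.8 to 91.0 with actinomycin D. It was 227 to 249 in IMR-32 with DMSO and 77.9 to 97.7 with THZ1, and 349 to 371 in SH-SY5Y with DMSO and 309 to 350 with THZ1. SH-SY5Y with MYCN had medians of 459 to 482, and of 245 to 261 with THZ1. Levels were lowest in Kelly with shGFP (44.7 to 67.7) and shMYCN (40.5 to 43.7). Control RNAs had been added in proportion to cell number, so that a loss of RNA per cell could show as a fall of most genes. The 40 brightest control probe sets changed by −0.04 to 0.01 on the log2 scale between the groups compared. The background probe sets averaged 4.02 in Kelly with DMSO, 4.09 in SH-SY5Y with DMSO, 2.38 with shGFP and 4.88 in SH-SY5Y with MYCN, so these last arrays formed sets of their own. Changes are log2 values ± standard error from limma with its adjusted p, on the deposited scale, fitted over all 28 arrays unless stated. The genes given first in each comparison had the largest changes among called genes whose 2 groups did not overlap, which 10% of genes show by chance with 3 against 3 arrays. The p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

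MYCN served as the check of the labels. Its brightest probe set had a mean of 13.29 ± 0.28 (SD, n = 3) in Kelly and 13.51 ± 0.07 (SD, n = 3) in IMR-32, against 7.17 ± 0.12 (SD, n = 3) in SH-SY5Y, all with DMSO. In SH-SY5Y with MYCN this probe set was lower (6.00, a change of −1.17 ± 0.17), while of its 3 other probe sets, here B, C and D, B rose from 6.23 to 10.06 (3.84 ± 0.16) and C by 2.47 ± 0.16. The brightest probe set and D (−0.99 ± 0.17) therefore did not register the added MYCN, and what part of the transcript the added copy carried is not given in the sources used here. With shMYCN, probe set B fell from 11.01 to 10.04 (−0.98 ± 0.18, adjusted p = 1.13e-05), C by 0.61 ± 0.18 (adjusted p = 0.00490) and D by 0.64 ± 0.18 (adjusted p = 0.00314), but the brightest one did not pass (−0.44 ± 0.19, adjusted p = 0.0517), and with equal array medians only B did (−0.60). MYC, the close relative of MYCN, stood at 9.67 in SH-SY5Y and near the background in Kelly (4.02) and IMR-32 (4.19). In SH-SY5Y with MYCN, MYC fell to 7.14 (−2.54 ± 0.18). CDK7 was higher in SH-SY5Y (9.78) than in Kelly (8.72; −1.06 ± 0.15) and IMR-32 (8.70; −1.07 ± 0.15), and it rose with MYCN (0.56 ± 0.17; 0.18 and not called with equal array medians).

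**Figure D1:**
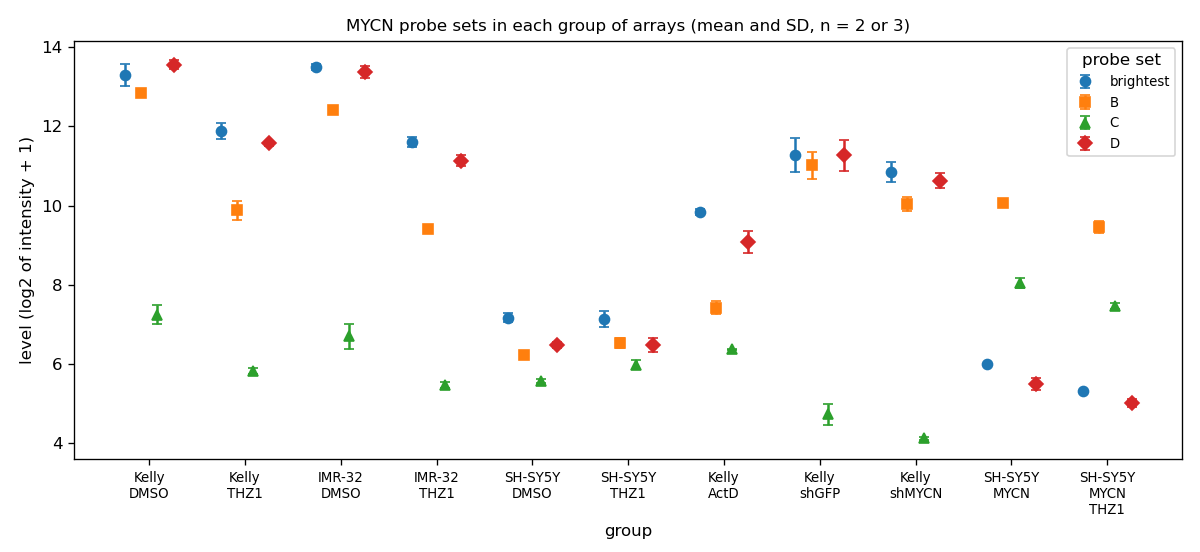
Mean log2 intensity with SD of the 4 MYCN probe sets in each group of 2 or 3 arrays. In SH-SY5Y with MYCN, probe set B reached 10.06 while the probe set brightest over all arrays lay at 6.00.

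The median change over the 11666 genes, taken for each array and averaged, summarizes the shift shared by most genes, and whether it equals a change of total RNA was not tested. With THZ1 it was −0.82 ± 0.06 (SD, n = 3 arrays) in Kelly and −1.003 ± 0.15 (SD, n = 3) in IMR-32, each relative to DMSO, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. Over all 18244 genes without the filter on level these medians were −0.52 and −0.58, and with equal array medians they turned to 0.38 and 0.43. In SH-SY5Y it was −0.01 ± 0.08 (SD, n = 3, exact p = 1). In SH-SY5Y with MYCN it was −0.75 ± 0.03 (SD, n = 2, exact p = 0.33, the smallest for 2 against 2; −0.55 without the filter and 0.15 with equal array medians). Actinomycin D gave a Kelly median of −0.82 ± 0.13 (SD, n = 2, exact p = 0.1, the smallest for 2 against 3; −0.54 without the filter and 0.502 with equal array medians), and THZ1 differed from it by 0.03 ± 0.05 (SD, n = 3, exact p = 0.7). The shMYCN median of −0.27 ± 0.08 (SD, n = 2) lay within the spread of the shGFP arrays (SD 0.36, exact p = 0.667). The SH-SY5Y median was higher with MYCN by 0.44 ± 0.03 (SD, n = 2, exact p = 0.1), beside a rise of the background probe sets of 0.79, whereas the background moved by −0.07 to 0.03 in the THZ1 comparisons within a line. Setting the medians of all arrays equal shifted the changes by other amounts: −1.20 in Kelly, −1.43 in IMR-32, −0.16 in SH-SY5Y, −0.89 in SH-SY5Y with MYCN and −1.32 for actinomycin D were taken out. It took out 0.13 for THZ1 against actinomycin D, −0.38 for shMYCN and 0.38 for MYCN in SH-SY5Y. After the data were seen a further scale was added, on which the median difference of each array from the mean of all arrays is 0 (below, equal median differences), which left median changes of −0.027 to 0.108 in the 13 comparisons. The split of the called genes of each comparison is given below on all 3 scales.

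**Figure D2:**
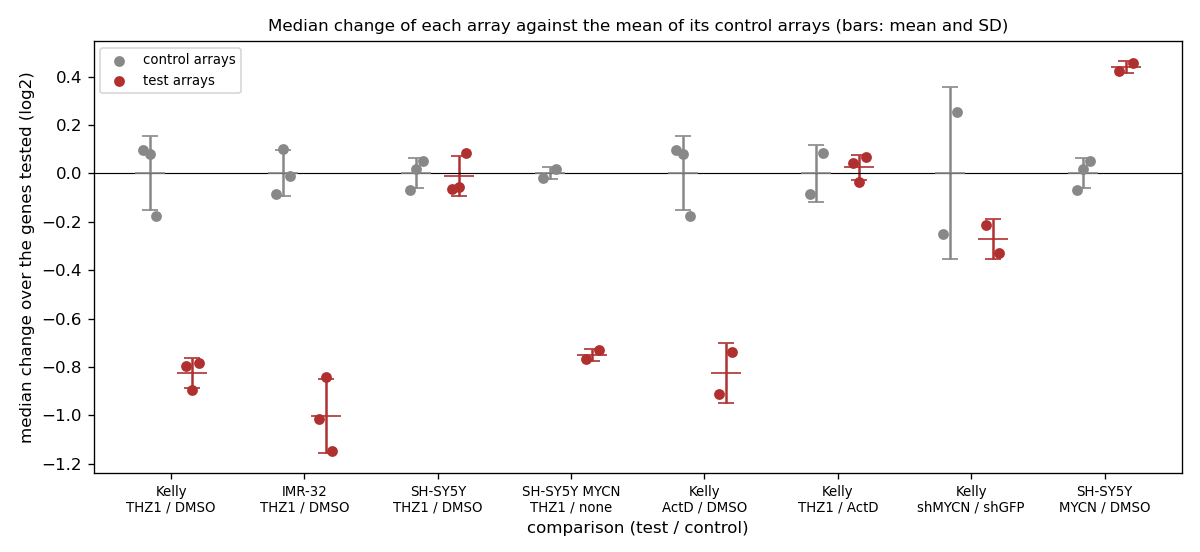
Median log2 change over 11666 genes, 1 point per array, for 8 comparisons, with control arrays beside the treated ones. All THZ1 arrays of Kelly and IMR-32 lie below their controls, and those of SH-SY5Y overlap them.

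The comparison of THZ1 with DMSO in Kelly asked which transcripts fall within hours of THZ1 treatment in a line with much MYCN (n = 3 arrays per group). DKK1, which encodes a secreted inhibitor of WNT signalling, fell most (−4.18 ± 0.13). It was followed by ZBED5, a gene derived from a transposon (−4.09 ± 0.16), MTFR2, a factor of mitochondrial fission (−3.90 ± 0.13), and JMJD6, a hydroxylase of RNA-processing proteins (−3.77 ± 0.14). XBP1, a transcription factor of the unfolded protein response (−3.71 ± 0.16), and ZNF557, a zinc finger gene (−3.68 ± 0.14), came next. The largest rises were of probe sets assigned to small nucleolar or Cajal body RNAs and histones. Whether such probe sets, here and below, read the mature RNAs or longer transcripts was not tested. SNORA65 (2.44 ± 0.15), SNORA2A (1.65 ± 0.16) and SNORA80E (1.61 ± 0.16) guide the modification of ribosomal RNA, and SCARNA20 (1.61 ± 0.17) does so for RNAs of Cajal bodies. H2AC17 (1.91 ± 0.17) and H2BC8 (1.75 ± 0.15) encode histones made during DNA replication, with probe sets that can read near-identical family members. MYCN fell from 13.29 to 11.88 (−1.42 ± 0.15; −0.22 and not called with equal array medians), and by more on its other bright probe sets, D (−1.98 ± 0.15) and B (−2.96 ± 0.14), both still lower with equal array medians (−0.78 and −1.76). CDK7 itself fell (−2.21 ± 0.15). MYC was near the background and its change of −0.58 ± 0.16 turned to 0.62 once the array medians were set equal.

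In Kelly 86.8% of all tested genes were called lower (median −0.81), so a list count near that share does not set the list apart. All 20 core transcription factors of the noradrenergic state, which specify sympathetic neurons, fell in Kelly (median −1.82), among them HAND2 (−2.81 ± 0.14), HAND1 (−2.67 ± 0.15), PHOX2A (−2.59 ± 0.15) and SOX11 (−2.46 ± 0.16). All 27 mitosis genes fell (median −1.52), with CENPA, the histone of centromeres (−3.51 ± 0.15), AURKA, a kinase of the spindle poles (−2.92 ± 0.15), and CCNB1, a cyclin (−2.85 ± 0.15), in front. In DNA repair 18 of 20 genes fell (median −1.29), led by the nuclease gene EXO1 (−3.25 ± 0.16) and by PALB2, a partner of BRCA proteins (−2.91 ± 0.16). Of the p53 targets 21 of 23 fell (median −1.44), with AEN (−3.11 ± 0.14) and GADD45A (−2.33 ± 0.15) as examples. Among genes of cell death, 18 of 20 fell (median −1.11), including MCL1, a short-lived protector from apoptosis (−2.39 ± 0.15), and XIAP, an inhibitor of caspases (−2.03 ± 0.16). In the stress response 18 of 19 fell (median −1.14), with DNAJB1 (−3.32 ± 0.15) and CEBPB (−2.997 ± 0.17) beside XBP1. Ribosome biogenesis lost 23 of 25 (median −1.11), led by PPAN (−3.44 ± 0.14), NOP16 (−2.96 ± 0.15) and RRS1 (−2.77 ± 0.15). Of the markers of noradrenergic and neuronal differentiation 16 of 26 fell (median −0.51), NEFL, a neurofilament, most (−1.18 ± 0.16, but 0.01 with equal array medians). None of the 28 cytosolic ribosomal proteins passed limma's test (median −0.04), or had an unadjusted p under 0.05, but with the array medians set equal all 28 were higher. In oxidative phosphorylation 9 of 28 fell (median −0.23), SDHA most (−0.86 ± 0.15), but all 28, SDHA included (0.34), were higher once the array medians were equal. Adjusted over the list alone, these counts were the same, except that 15 fell in the noradrenergic and neuronal list and 5 fell in the oxidative phosphorylation list.

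Limma called 10163 of 11666 genes in Kelly, 35 higher and 10128 lower, and 4615 of them changed at least 2-fold. With the array medians set equal it called 9430, 6844 higher and 2586 lower, and with equal median differences 8507, 4656 higher and 3851 lower, so that the direction of the smaller changes rests on the scaling. Against all other genes, camera placed the core transcription factors (adjusted p = 5.83e-07), mitosis (1.11e-04), DNA repair (0.0227) and the p53 targets (0.0409) lower. It placed the ribosomal proteins (8.93e-16), oxidative phosphorylation (1.24e-08) and the noradrenergic and neuronal markers (0.00397) higher, although the medians and means of these lists were below 0. None of these 7 calls among the 21 lists held with an estimated correlation (adjusted p = 0.746 for each, none with an unadjusted p under 0.05). The treated levels of ZBED5, MTFR2, JMJD6 and ZNF557 were near the background, which limits how large a fall can be measured, and SNORA2A rose from near it.

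IMR-32 asked the same of the other line with much MYCN (n = 3 per group). Its largest falls were DKK1 again (−5.91 ± 0.13), INSIG1, a brake on sterol synthesis (−5.31 ± 0.15), UMPS, an enzyme of pyrimidine synthesis (−4.73 ± 0.14), and MRPL17 of the mitochondrial ribosome (−4.71 ± 0.15). PTCH1, the receptor of Hedgehog proteins (−4.58 ± 0.14), and LONRF1 (−4.50 ± 0.15) followed. SNORA65 (2.58 ± 0.15), SNORA2A (1.83 ± 0.16) and the small nucleolar RNA host SNHG17 (1.83 ± 0.15) rose, as did the histone genes H3C1 (2.35 ± 0.15) and H2AC17 (2.22 ± 0.17) and DPY19L3, a mannosyltransferase gene (1.96 ± 0.15, lost when all its probe sets were averaged). MYCN fell from 13.51 to 11.60 (−1.91 ± 0.15) and CDK7 fell (−2.66 ± 0.15), while MYC stayed near the background (−0.09 ± 0.16, not past the test). All 20 core transcription factors fell (median −2.17), with PHOX2A (−3.90 ± 0.15), ISL1 (−3.62 ± 0.14) and EYA1 (−2.94 ± 0.15) in front. All 27 genes of S phase fell (median −1.39), including CCNE1, the cyclin of S phase entry (−3.93 ± 0.14), and CDC6, which loads the replicative helicase (−3.75 ± 0.17), and 26 of 27 mitosis genes did (median −1.55), CENPA most (−4.17 ± 0.15). All 14 genes of cholesterol synthesis fell (median −1.46), among them SQLE (−3.20 ± 0.14) and MSMO1 (−2.70 ± 0.15). Ribosome biogenesis lost 23 of 25 (median −1.66), with NOP16 (−3.76 ± 0.15) and POLR1B, a subunit of RNA polymerase I (−3.36 ± 0.14). The RNA polymerase II machinery lost 25 of 26 (median −1.46), with GTF2H1, a subunit of the factor that holds CDK7 (−3.12 ± 0.15), and MED13 of the Mediator complex (−3.08 ± 0.16). In the stress response 17 fell and 1 rose of 19 (median −1.64), XBP1 most (−4.47 ± 0.16), and of the mesenchymal markers 15 fell and 1 rose of 19 (median −0.69), TWIST1 most (−3.87 ± 0.15), though camera placed the latter list higher, uncalled (adjusted p = 0.219).

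The immediate early genes, which answer growth signals within minutes, were mixed in IMR-32, with 12 of 20 lower and 3 higher (median −0.58), DUSP6 (−2.07 ± 0.15) and EGR1 (−1.87 ± 0.15) among the lower ones. Of the histones 5 of 9 fell (median −0.30), H2AX most (−2.64 ± 0.15), and of the interferon genes 5 of 9 (median −0.35), IRF9 most (−1.12 ± 0.15, but 0.31 with equal array medians). Of the ribosomal proteins only RPL7 passed, with a rise (0.37 ± 0.15, lost without single arrays), and the median of the 28 genes was 0.02, with all 28 higher once the array medians were set equal. These counts stayed the same when adjusted over the list alone, except that 24 fell in the ribosome biogenesis list and 0 rose in the ribosomal protein list. Limma called 10303 genes, 55 higher and 10248 lower, 5862 of them at least 2-fold, and with equal array medians 9807, 6883 higher and 2924 lower (4883 and 4437 with equal median differences). By camera the core transcription factors (adjusted p = 3.44e-05), S phase (0.0187), mitosis (0.0187) and ribosome biogenesis (0.0492) were lower than other genes, and the ribosomal proteins (1.20e-18) higher. The immediate early (0.0176), histone (0.0187), interferon (0.0176), oxidative phosphorylation (2.50e-07) and noradrenergic and neuronal (0.0176) lists and that of immune and endothelial markers (0.0336) were also placed higher, against negative medians and means. With an estimated correlation none of these 11 calls held (adjusted p = 0.725 for each, 1 of the 21 lists with an unadjusted p under 0.05). Treated levels of INSIG1, LONRF1, XBP1, DUSP6 and EGR1 were near the background, and H3C1 and DPY19L3 rose from near it, so the size of their rises is uncertain.

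In SH-SY5Y the comparison asked for the response of a line with little MYCN (n = 3 per group). KRCC1 (−2.41 ± 0.14), a gene of little known function, and PPP1R10, a regulatory subunit of a nuclear phosphatase (−2.29 ± 0.14), fell most. GDF6, a growth factor of the BMP family (−2.08 ± 0.17), IFT70A of the ciliary transport (−2.03 ± 0.17), and the microRNA gene MIR21 (−1.84 ± 0.16) followed. PHF12, a chromatin reader, rose most (2.10 ± 0.13), before DPY19L3 (1.73 ± 0.15), DMXL1, a regulator of the proton pump (1.37 ± 0.15), H2BC8 (1.20 ± 0.15), FZR1, an activator of the anaphase-promoting complex (1.18 ± 0.15), and the histone methyltransferase gene KMT5B (1.12 ± 0.16). When all probe sets of a gene were averaged, PHF12 (0.70) and DPY19L3 (0.55) stayed called but rose less than H2BC8 (1.02), KMT5B turned to −0.43, and DMXL1 and ATM were no longer called. MYCN (−0.03 ± 0.15), MYC (−0.24 ± 0.16) and CDK7 (−0.38 ± 0.15, adjusted p = 0.0806) did not pass. Among all tested genes 12.4% were called lower and 2.78% higher. Of the core transcription factors 3 of 20 fell (median −0.15), TBX2 most (−0.68 ± 0.14). In DNA repair 9 fell and 1 rose of 20 (median −0.35), with ERCC4, an endonuclease subunit (−1.82 ± 0.15), and PALB2 (−0.84 ± 0.16) lower and the damage kinase gene ATM (1.08 ± 0.14) higher. In the RNA polymerase II list 2 rose and 3 fell of 26, POLR2A, the largest subunit (0.83 ± 0.14), among the risen and GTF2H1 (−0.96 ± 0.15) among the fallen. Of the p53 targets 4 rose and 1 fell of 23 (median 0.08), with PPM1D (0.80 ± 0.15) and ZMAT3 (0.70 ± 0.14) higher. Of the immediate early genes 4 fell and 2 rose of 20, JUN most (−1.10 ± 0.15). Of the mitosis genes 3 of 27 fell (median −0.20), CENPA most (−1.14 ± 0.15). Of the noradrenergic and neuronal markers 2 rose, NEFM (0.53 ± 0.17) and CHGB (0.46 ± 0.15), both lost without single arrays, and 24 did not pass (median 0.17). By limma no gene passed among the 28 ribosomal proteins (median 0.09), 28 of oxidative phosphorylation (median 0.16) and 26 of growth and metabolism (median 0.05), where 0, 3 and 1 had an unadjusted p under 0.05. With equal array medians 24, 26 and 13 of them were higher. The counts adjusted over the list alone were the same, except that 1 rose in the core transcription factor list, 10 fell in the DNA repair list and 5 rose and 2 fell in the p53 list.

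Limma called 1774 genes in SH-SY5Y, 324 higher and 1450 lower, and 174 of them changed at least 2-fold. Setting the array medians equal gave 5484 calls, 4036 higher and 1448 lower, and with equal median differences 3882, 1798 higher and 2084 lower, so the split of directions rests on the scaling here too. Fitted on its own 6 arrays, the comparison gave 2666 calls. Camera placed DNA repair lower (adjusted p = 0.00463) and the noradrenergic and neuronal markers (0.00463), oxidative phosphorylation (0.00463) and ribosomal proteins (0.0384) higher than other genes, none with an estimated correlation (adjusted p = 0.948 for each, no list with an unadjusted p under 0.05). In the RNA polymerase II list (median 0.03, mean −0.03, placed higher) and the immediate early list (median 0.06, mean −0.03, placed higher) median and mean differed in sign, and neither list was called (adjusted p = 0.706 for each). Treated levels of GDF6 and IFT70A were near the background, and DPY19L3 rose from near it.

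Whether the response differed between lines was tested directly as the difference of the THZ1 effects. The fall in Kelly exceeded that in SH-SY5Y for SLC2A4RG, a regulator of a glucose transporter gene (−3.41 ± 0.24), WEE1, the kinase that holds back mitosis (−3.40 ± 0.20), DKK1 (−3.40 ± 0.19), RGS2, a brake on G protein signalling (−3.38 ± 0.21), KCNJ8, a potassium channel gene (−3.35 ± 0.21), and TWIST1 (−3.35 ± 0.22). IMR-32 exceeded SH-SY5Y for DKK1 (−5.13 ± 0.19), INSIG1 (−4.79 ± 0.21), the growth factor gene PGF (−4.46 ± 0.21), UMPS (−4.22 ± 0.20), the ubiquitin protease gene USP38 (−4.22 ± 0.24) and ASF1A, a histone chaperone (−4.13 ± 0.22). In the other direction SNORA65 differed in Kelly (1.88 ± 0.22) and IMR-32 (2.02 ± 0.22), SCARNA20 in Kelly (1.57 ± 0.24), and H3C1 (2.06 ± 0.21) and H2AC17 (1.52 ± 0.24) in IMR-32. KRCC1 (2.12 ± 0.20), ANKRD1 (1.86 ± 0.20), BEND7 (1.48 ± 0.21) and TLR4 (1.46 ± 0.21) in Kelly, and ANKRD1 (1.63 ± 0.20), GBX2 (1.45 ± 0.23) and CCN2 (1.44 ± 0.24) in IMR-32, were near the background there with DMSO, where no fall could be measured. MYCN differed by −1.39 ± 0.22 in Kelly (−0.35 and not called with equal array medians) and −1.88 ± 0.22 in IMR-32, and CDK7 by −1.83 ± 0.21 and −2.28 ± 0.21. MYC differed in neither (−0.34 ± 0.22 and 0.15 ± 0.22), but by 0.70 and 1.42 with equal array medians, at levels near the background. The difference was called lower for 81.1% of all tested genes in Kelly and 84.0% in IMR-32. All 20 core transcription factors fell more in Kelly (median −1.77), HAND1 (−2.73 ± 0.22) and HAND2 (−2.45 ± 0.20) in front, and all 20 in IMR-32 (median −2.01), ISL1 most (−3.71 ± 0.20). All 27 mitosis genes fell more in Kelly (median −1.41), AURKA most (−2.72 ± 0.21), and 26 of them in IMR-32 (median −1.45). Of the p53 targets 21 of 23 fell more in Kelly (median −1.30), AEN (−2.83 ± 0.19) and PPM1D (−2.74 ± 0.22) among them, and 21 in IMR-32 (median −1.60). By limma no ribosomal protein differed in Kelly (median −0.14) or IMR-32 (median −0.10), or had an unadjusted p under 0.05, but with equal array medians all 28 were higher in each. No count of these lists differed when adjusted over the list alone. In IMR-32, adjusted over the list alone, these counts were the same.

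The difference was called for 9531 genes in Kelly (9463 lower, 68 higher) and 9860 in IMR-32 (9799 lower, 61 higher), 4347 and 5691 of them at least 2-fold. With equal array medians the counts were 6337 (2080 lower, 4257 higher) and 7992 (2555 lower, 5437 higher), and with equal median differences 5443 (2881 lower, 2562 higher) and 6987 (3713 lower, 3274 higher). Camera called 5 lists in Kelly and 10 in IMR-32. It placed the core transcription factors lower (adjusted p = 2.45e-07 in Kelly and 6.89e-06 in IMR-32), with mitosis (3.98e-04) and the p53 targets (9.04e-04) in Kelly and S phase (0.0105), ribosome biogenesis (0.0264), the stress response (0.0279) and cholesterol synthesis (0.0283) in IMR-32. It placed the ribosomal proteins (6.22e-11 and 3.50e-14) and oxidative phosphorylation (1.65e-04 and 2.20e-04) higher, and in IMR-32 the immediate early (0.0105), interferon (0.0115) and immune and endothelial (0.0475) lists, although the medians and means of all these lists were below 0. With an estimated correlation no list was called (adjusted p = 0.736 in Kelly and 0.749 in IMR-32), and none had an unadjusted p under 0.05. Treated levels of KCNJ8 in Kelly and of INSIG1 and USP38 in IMR-32 were near the background, as was H3C1 with DMSO in IMR-32 and SH-SY5Y.

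Adding MYCN to SH-SY5Y and then THZ1 asked whether MYCN changes the response of a line that has little of it (n = 2 per group). The labels give neither DMSO nor a time for its arrays without THZ1. An effect of the vehicle is therefore not separated from that of THZ1, here or in the difference from SH-SY5Y. PPP1R10 (−3.83 ± 0.17), the zinc finger gene ZNF764 (−3.01 ± 0.17), PPAN (−2.92 ± 0.17), LCMT2, a transfer RNA methyltransferase (−2.84 ± 0.18), MOCS3, a sulfur carrier activator (−2.76 ± 0.20), and CYREN, a modulator of end joining (−2.76 ± 0.18), fell most. PHF12 (1.89 ± 0.16), DPY19L3 (1.702 ± 0.18), HUS1B, a checkpoint clamp gene (1.47 ± 0.22), EID3 (1.30 ± 0.17), DMXL1 (1.004 ± 0.18) and SNORA65 (0.93 ± 0.19) rose, but averaged over all their probe sets DMXL1 turned to −0.16 and PHF12 and DPY19L3 were not called. MYC (−1.20 ± 0.19), CDK7 (−1.11 ± 0.18) and the brightest MYCN probe set (−0.69 ± 0.19) fell, none of them with equal array medians (−0.31, −0.22 and 0.20), and MYCN probe set B fell from 10.06 to 9.46 (−0.60 ± 0.18; 0.29 and not called with equal array medians). That MYCN probe set fell by 2.96 ± 0.14 in Kelly, and there it stayed lower. All 27 genes of S phase fell (median −0.86), with GINS1 of the replicative helicase (−1.83 ± 0.17) and RPA2 (−1.56 ± 0.18), and all 19 mesenchymal markers (median −0.83), with SNAI2 (−2.08 ± 0.16) and CCN2 (−1.68 ± 0.21). Core transcription factors fell in 19 of 20 cases (median −1.04), TBX2 (−1.52 ± 0.17) and PHOX2A (−1.43 ± 0.18) most, and all 11 MYC family genes did (median −0.89), MLX, a partner in glucose sensing (−1.40 ± 0.18), most. Of the immediate early genes 16 of 20 fell (median −0.86), JUN (−2.32 ± 0.18) and DUSP1 (−2.21 ± 0.19) most. By limma no ribosomal protein passed (median −0.13, 1 with an unadjusted p under 0.05), and all 28 were higher with equal array medians. The fall was larger than in SH-SY5Y without MYCN for FCN2, a lectin gene (−1.81 ± 0.35), PPAN (−1.72 ± 0.22), ZNF764 (−1.72 ± 0.22), TNNI1 (−1.698 ± 0.24), MYPOP, a repressor (−1.697 ± 0.24), HMOX1, the heme oxygenase gene (−1.69 ± 0.23), MYC (−0.96 ± 0.25) and CDK7 (−0.73 ± 0.24). In the list of core transcription factors 18 of 20 fell more (median −0.79), HAND1 most (−1.38 ± 0.24), and of the growth and metabolism genes 18 of 26 (median −0.70), CAD most (−1.19 ± 0.22), although camera placed the latter list higher, uncalled (adjusted p = 0.523). Of these genes FCN2, MYC, CDK7, HAND1 and CAD were not called with equal array medians. Adjusted over the list alone, only the counts of the difference changed, to 19 core transcription factors and 17 growth and metabolism genes.

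Limma called 10287 genes for THZ1 in SH-SY5Y with MYCN (24 higher, 10263 lower, 3131 at least 2-fold), and 5103 with equal array medians (3319 higher, 1784 lower) or 4264 with equal median differences (1777 higher, 2487 lower). The difference from SH-SY5Y was called for 9775, all lower (none higher at an unadjusted p under 0.05 either), 1597 of them at least 2-fold. With equal array medians it was called for 240 (75 higher, 165 lower) and with equal median differences for 362 (118 higher, 244 lower). Camera called the ribosomal proteins (5.57e-15) and oxidative phosphorylation (2.63e-06) higher than other genes, against negative medians and means, and neither held with an estimated correlation (adjusted p = 0.632 and 0.937). For the difference it called the same lists higher (2.24e-16 and 0.00746), again against negative medians and means and not with an estimated correlation (adjusted p = 0.973 for each). The treated levels of PPP1R10 and of the brightest MYCN probe set were near the background of these arrays, and DPY19L3, HUS1B and EID3 rose from near it.

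Actinomycin D in Kelly asked what a general stop of transcription does in the same time (n = 2, against 3 with DMSO). TSC22D1, a leucine zipper regulator (−5.58 ± 0.18), ID2, an inhibitor of differentiation (−5.57 ± 0.17), RGS2 (−5.51 ± 0.17), INSM2, a neuroendocrine zinc finger gene (−5.31 ± 0.15), PPM1D, a phosphatase of the p53 pathway (−5.30 ± 0.17), and FBXO5, an inhibitor of the anaphase-promoting complex (−5.25 ± 0.18), fell most. All of the 6 largest rises were of probe sets assigned to small nucleolar or Cajal body RNAs: SNORA80E (2.75 ± 0.17), SNORA2A (2.66 ± 0.17), SNORA6 (2.505 ± 0.17), SNORA13 (2.12 ± 0.18), SNORA21 (1.95 ± 0.16) and SCARNA20 (1.79 ± 0.19). MYCN fell from 13.29 to 9.84 (−3.45 ± 0.17) and CDK7 to near the background (−3.80 ± 0.17), where MYC lay throughout (−0.88 ± 0.18, but 0.44 with equal array medians). All 20 core transcription factors fell (median −2.65), with HAND1 (−3.96 ± 0.17), GATA2 (−3.88 ± 0.16) and ISL1 (−3.54 ± 0.16) in front, and all 20 immediate early genes (median −1.59), with JUN (−3.97 ± 0.17), KLF10 (−3.94 ± 0.15) and DUSP6 (−3.86 ± 0.17). All 11 MYC family genes fell (median −1.39), MYCN and MGA (−2.41 ± 0.17) most. Mitosis lost 26 of 27 (median −1.58), with KIF23, a motor of cell division (−3.38 ± 0.20), and CCNB1 (−3.08 ± 0.17). The stress response lost 17 of 19 (median −1.73), with XBP1 (−4.46 ± 0.18) and DNAJB1 (−3.98 ± 0.16), and the p53 targets 19 of 23 (median −1.33), with PLK2 (−3.44 ± 0.17). In cell death 18 of 20 fell (median −1.18), MCL1 (−4.45 ± 0.16) and BBC3 (−3.09 ± 0.20) most. RPL7 (0.62 ± 0.17) and RPS25 (0.44 ± 0.14) rose among the 28 ribosomal proteins (median 0.06), all of them higher with equal array medians, while RPS25 turned to −0.36 when all its probe sets were averaged and neither passed when the median control RNA was set equal. No count of these lists differed when adjusted over the list alone, except that 1 rose in the ribosomal protein list. Limma called 9692 genes (68 higher, 9624 lower, 4789 at least 2-fold), and 9740 with equal array medians (7184 higher, 2556 lower; 4538 and 3894 with equal median differences). Camera called the core transcription factors (adjusted p = 4.47e-09), immediate early genes (3.26e-04), mitosis (0.00153), stress response (0.0103), MYC family (0.0127), DNA repair (0.0207) and p53 targets (0.0422) lower and the ribosomal proteins (6.87e-16) higher. Against negative medians and means it called oxidative phosphorylation (4.47e-09), growth and metabolism (0.0114) and the noradrenergic and neuronal markers (0.0123) higher, and none of the 11 held with an estimated correlation (adjusted p = 0.742 for each). Treated levels of PPM1D, JUN, KLF10, DUSP6, MGA, XBP1, PLK2 and BBC3 were near the background, which limits how large a fall can be measured, and SNORA2A rose from near it.

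THZ1 was compared with actinomycin D in Kelly to tell the response to THZ1 from that to a general stop. ID2 was higher with THZ1 (4.73 ± 0.17), as were ZNF503 (3.54 ± 0.18), PPM1D (3.36 ± 0.17), RCL1, a factor of ribosomal RNA processing (3.13 ± 0.16), SCAF8, which binds RNA polymerase II (3.09 ± 0.18), and TSC22D1 (3.05 ± 0.18). SNORA6 (−1.78 ± 0.17), CNIH2, a partner of glutamate receptors (−1.55 ± 0.17), CENPA (−1.50 ± 0.17), KCTD18 (−1.44 ± 0.16), MAU2, a cohesin loader (−1.41 ± 0.16), and SNORA21 (−1.36 ± 0.16) were lower. MYCN (2.04 ± 0.17) and CDK7 (1.59 ± 0.17) were higher with THZ1 and MYC was not called (0.30 ± 0.18). MYCN probe sets B (2.46 ± 0.16) and D (2.49 ± 0.17) were higher too, but the fainter C was lower (−0.54 ± 0.16). Of the immediate early genes 11 of 20 were higher and none lower (median 0.62), KLF10 (2.996 ± 0.15), JUN (2.11 ± 0.17) and BTG1 (2.10 ± 0.16) most, and of the core transcription factors 12 of 20 (median 0.84), GATA2 (2.37 ± 0.16) and SOX4 (1.75 ± 0.15) most. In the stress response 11 were higher and 1 lower of 19 (median 0.63), DDIT4 (1.75 ± 0.19) and HSPA1A (1.15 ± 0.19) higher and ATF4 (−0.84 ± 0.15) lower. In cell death 4 were higher and 1 lower of 20 (median 0.11), MCL1 most (2.06 ± 0.16). Cholesterol synthesis had 3 of 14 lower (median −0.22). Adjusted over the list alone, these counts were the same, except that 12 were higher in the immediate early list, 13 were higher in the core transcription factor list and 12 were higher in the stress response list. Limma called 2574 genes (1740 higher with THZ1, 834 lower, 606 at least 2-fold), but 5126 with equal array medians (1861 higher, 3265 lower), 4548 with equal median differences (2421 higher, 2127 lower), and 1604 without the first actinomycin D array. Camera placed the immediate early genes (adjusted p = 6.09e-10), core transcription factors (5.18e-06) and stress response (0.00883) higher, none with an estimated correlation (adjusted p = 0.888, 0.986 and 0.986), but the immediate early genes were higher with it at equal median differences (adjusted p = 0.00846). ZNF503, PPM1D, RCL1, CDK7, KLF10, JUN and DDIT4 were near the background with actinomycin D, and KCTD18 with THZ1.

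Knockdown of MYCN in Kelly asked which transcripts depend on MYCN (n = 2 per group). DLEU2, a host of microRNAs (−3.95 ± 0.18), CSRP2, a LIM domain gene (−3.87 ± 0.18), KCTD12 (−3.78 ± 0.18), CDK2AP1, a cell cycle regulator (−3.77 ± 0.17), GLRX5 of iron-sulfur cluster assembly (−3.73 ± 0.18) and the laminin gene LAMA1 (−3.56 ± 0.18) fell most. SNORA12 (2.497 ± 0.19), the lysosomal fucosidase gene FUCA1 (2.34 ± 0.19), the flippase gene ATP10D (2.30 ± 0.20), the deubiquitinase gene CYLD (2.23 ± 0.18), SMIM14 (2.22 ± 0.17) and YPEL3, a growth suppressor (2.14 ± 0.18), rose most. MYC (−0.01 ± 0.19) and CDK7 (−0.34 ± 0.18) were not called. Of the genes of S phase 24 of 27 fell (median −1.32), with CDC45 of the replicative helicase (−2.64 ± 0.18) and UHRF1, which keeps DNA methylation (−2.09 ± 0.18). Mitosis lost 24 of 27 (median −1.05), with the motor gene KIF11 (−3.12 ± 0.20) and MKI67, a marker of dividing cells (−2.36 ± 0.20), and DNA repair 19 of 20 (median −1.004), with FANCI (−2.07 ± 0.19). Of the growth and metabolism genes known as MYC targets 20 of 26 fell (median −1.02), with HK2 of glycolysis (−2.35 ± 0.17), PHGDH of serine synthesis (−2.34 ± 0.17) and SHMT2 (−2.30 ± 0.18), and of ribosome biogenesis 22 of 25 (median −0.96), with RRP12 (−2.18 ± 0.18) and NCL, the nucleolin gene (−1.88 ± 0.17). In the stress response 13 fell and 1 rose of 19 (median −0.90), with HSP90AA1 (−2.92 ± 0.19) and HSPH1 (−2.56 ± 0.21) lower, and of the core transcription factors 12 of 20 fell (median −0.70), with INSM1 (−2.56 ± 0.18) and LMO3 (−2.34 ± 0.19). Of the noradrenergic and neuronal markers 14 fell and 6 rose of 26 (median −0.52), with DBH (−3.02 ± 0.17) and TH (−2.05 ± 0.22), enzymes of noradrenaline synthesis, lower. RPS19 fell (−1.04 ± 0.16) and the other 27 ribosomal proteins were not called (median of all 0.11, with 26 higher and 1 lower at equal array medians). These counts stayed the same when adjusted over the list alone, except that 25 fell in the mitosis list, 1 rose in the DNA repair list, 21 fell in the growth and metabolism list and 2 rose and 13 fell in the core transcription factor list. Limma called 5577 genes (1082 higher, 4495 lower, 2104 at least 2-fold), 6985 with equal array medians (3832 higher, 3153 lower), 6750 with equal median differences (3114 higher, 3636 lower) and 3558 on the 4 arrays alone. Camera placed S phase (adjusted p = 2.93e-07), growth and metabolism (7.60e-06), mitosis (1.92e-05), ribosome biogenesis (3.78e-05), DNA repair (6.14e-04), stress response (0.00377) and core transcription factors (0.0298) lower and ribosomal proteins (0.00215) higher, none with an estimated correlation (adjusted p = 0.987 for each). CSRP2 and INSM1 fell to near the background and FUCA1 rose from it.

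SH-SY5Y with MYCN was compared with SH-SY5Y given DMSO to ask what MYCN raises, though the vehicle of the former is not given in the sources used here (n = 2 against 3). TMEM100, a membrane adaptor gene (4.802 ± 0.17), AMIGO2, a cell adhesion gene (4.70 ± 0.18), CCDC85A (3.90 ± 0.18), the annexin gene ANXA1 (3.66 ± 0.17), PTPRC, the CD45 gene of blood cells (3.58 ± 0.19), and MECOM, a zinc finger transcription factor gene (3.45 ± 0.17), rose most. SCG2 (−3.69 ± 0.18) and CHGB (−2.74 ± 0.16) of secretory granules, the integrin gene ITGA9 (−2.75 ± 0.15), the cytokine gene IL15 (−2.74 ± 0.23), the complement gene C7 (−2.68 ± 0.20) and PDGFRA, a growth factor receptor gene (−2.68 ± 0.18), fell most. All 28 ribosomal proteins rose (median 1.02), RPS3 (1.41 ± 0.14) and RPL18 (1.17 ± 0.14) among them, and all 28 were still higher with equal array medians. Ribosome biogenesis gained 23 of 25 (median 0.91), with RRP12 (2.05 ± 0.16) and FBL, the fibrillarin gene (1.42 ± 0.15), and growth and metabolism 25 of 26 (median 0.91), with the amino acid carrier SLC7A5 (1.88 ± 0.15) and SRM of spermidine synthesis (1.47 ± 0.16). Oxidative phosphorylation gained 25 and lost 1 of 28 (median 0.96), COX5B (1.20 ± 0.16) among the gains. Of the p53 targets 20 of 23 rose (median 1.001), with CDKN1A, the p21 gene (2.04 ± 0.15), and PLK3 (1.60 ± 0.16). In the MYC family MXI1 (1.96 ± 0.15), MAX (1.54 ± 0.16) and MNT (1.48 ± 0.17) rose, making 6 higher and 2 lower of 11 (median 1.05). Of the noradrenergic and neuronal markers 17 of 26 fell and 4 rose (median −1.38), with DCX, a marker of young neurons (−2.60 ± 0.16), and DDC of dopamine synthesis (−2.45 ± 0.16) lower. Mitosis had 7 lower and 3 higher of 27 (median −0.02), NEK2 (−1.03 ± 0.18) and KIF20A (−1.01 ± 0.17) lower and TTK (0.86 ± 0.18) higher. Of 4 tested marker genes of immune and endothelial cells 3 rose (median 1.01), and of 3 of Schwann and glial cells 2 did (median 0.47). The counts adjusted over the list alone were the same, except that 2 fell in the oxidative phosphorylation list, 21 rose in the p53 list and 6 fell in the mitosis list.

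Limma called 7567 genes between SH-SY5Y with MYCN and with DMSO (6497 higher, 1070 lower, 1460 at least 2-fold), and with equal array medians 6670 (3598 higher, 3072 lower; 3429 and 3254 with equal median differences). Camera placed the noradrenergic and neuronal markers lower (adjusted p = 2.68e-23, 0.314 with an estimated correlation but 0.0205 at equal median differences as well), with mitosis (4.29e-04) and the core transcription factors (0.0396, 0.984 with an estimated correlation), although the median (0.07) and mean (0.03) of the latter were above 0. It placed the ribosomal proteins (1.87e-08), growth and metabolism (8.34e-06), p53 targets (1.80e-04), ribosome biogenesis (2.24e-04) and oxidative phosphorylation (4.29e-04) higher. With an estimated correlation mitosis and these 5 were lost (adjusted p = 0.874 for each). ITGA9 and IL15 fell to near the background, which was itself 0.79 higher in these arrays, and CCDC85A, PTPRC and MECOM rose from it.

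The lines were compared with DMSO to show the levels from which the drug acted (n = 3 per group). Kelly exceeded SH-SY5Y for TUBA1C, a tubulin gene (6.31 ± 0.16), MYCN (6.12 ± 0.15), the tumour antigen gene MAGEA1 (5.55 ± 0.20), EPB41L3 (5.44 ± 0.18), the neuronal filament gene PRPH (5.24 ± 0.16) and the moesin gene MSN (5.19 ± 0.14). It was lower for the matrix gene MGP (−9.50 ± 0.15), the protease inhibitor gene TFPI2 (−9.27 ± 0.16), S100A10 (−8.57 ± 0.16), the basement membrane gene NID1 (−7.82 ± 0.19), COL3A1 (−7.73 ± 0.15) and the gap junction gene GJA1 (−7.57 ± 0.16), all near the background in Kelly. IMR-32 exceeded SH-SY5Y for the transcription factor genes ZIC2 (7.06 ± 0.15), NHLH2 (6.90 ± 0.16) and EBF3 (6.04 ± 0.17), the receptor gene GFRA2 (6.66 ± 0.15) and MYCN (6.34 ± 0.15). It was lower for GNG11 (−9.45 ± 0.17), TFPI2 (−9.40 ± 0.16), the neuropeptide gene NPY (−8.63 ± 0.15), C7 (−8.36 ± 0.18), S100A10 (−8.26 ± 0.16) and COL3A1 (−7.87 ± 0.15). MYC was lower in Kelly (−5.65 ± 0.16) and IMR-32 (−5.48 ± 0.16). All 19 mesenchymal markers were lower in Kelly (median −3.18), VIM (−5.02 ± 0.15) and FN1 (−5.01 ± 0.15) among them, and 17 in IMR-32 (median −1.75), TGFBR2 (−5.37 ± 0.16) among them. Of the noradrenergic and neuronal markers 10 were higher and 9 lower of 26 in Kelly, with SLC18A2 (3.56 ± 0.17) and SCG2 (−4.68 ± 0.16), and 4 and 17 in IMR-32, with RET (−5.33 ± 0.14). In Kelly the median of these markers was 0.20 and their mean −0.04, and camera placed them higher (adjusted p = 3.40e-04, 0.725 with an estimated correlation). All 9 interferon genes were lower in Kelly (median −1.41), ISG15 among them (−2.501 ± 0.13), and 8 in IMR-32, while IFI44 was higher there (3.22 ± 0.15). Of the p53 targets 18 of 23 were lower and 1 higher in Kelly (median −1.01), CDKN1A most (−3.66 ± 0.14), and 16 lower and 2 higher in IMR-32, TIGAR lowest (−4.08 ± 0.16). Of the histones 6 of 9 were lower and 2 higher in Kelly and 7 lower in IMR-32, with H2BC12 lower in IMR-32 (−2.91 ± 0.16), while camera placed the list higher in Kelly against a median of −0.65, uncalled (adjusted p = 0.764). No count of these lists differed when adjusted over the list alone. In IMR-32, adjusted over the list alone, these counts were the same, except that 5 were higher and 19 were lower in the noradrenergic and neuronal list. Limma called 8702 genes for Kelly (889 higher, 7813 lower, 3576 at least 2-fold) and 8578 for IMR-32 (1120 higher, 7458 lower, 3279 at least 2-fold). At equal array medians 5254 were higher and 3398 lower in Kelly, and 4458 and 3663 in IMR-32, and with equal median differences 4545 and 3839, and 4426 and 3726. Camera called 14 lists in Kelly and 7 in IMR-32. It placed the mesenchymal markers (adjusted p = 1.06e-07 and 7.13e-05) and immediate early genes (0.0109 and 0.0295) lower, and in Kelly the interferon genes (0.0128) and p53 targets (0.029). Placed higher were the ribosomal proteins (3.08e-04 and 2.27e-04), growth and metabolism (3.46e-04 and 0.0016), S phase (0.00104 and 0.0162) and DNA repair (0.0163 and 0.0478), in IMR-32 the MYC family (0.0122), and in Kelly oxidative phosphorylation (3.46e-04), ribosome biogenesis (0.00104), mitosis (0.0084), cholesterol synthesis (0.0127), the core transcription factors (0.0418) and the noradrenergic and neuronal markers. Of those placed higher only the ribosomal proteins and the MYC family had both median and mean above 0. No list was called with an estimated correlation (adjusted p = 0.424 or more in Kelly and 0.953 or more in IMR-32), but at equal median differences as well the mesenchymal markers were lower in Kelly (adjusted p = 0.0190). In IMR-32 GNG11, TFPI2, C7, S100A10, COL3A1, TGFBR2 and TIGAR were near the background, and in SH-SY5Y MAGEA1, EPB41L3, ZIC2, NHLH2 and EBF3.

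**Figure D3:**
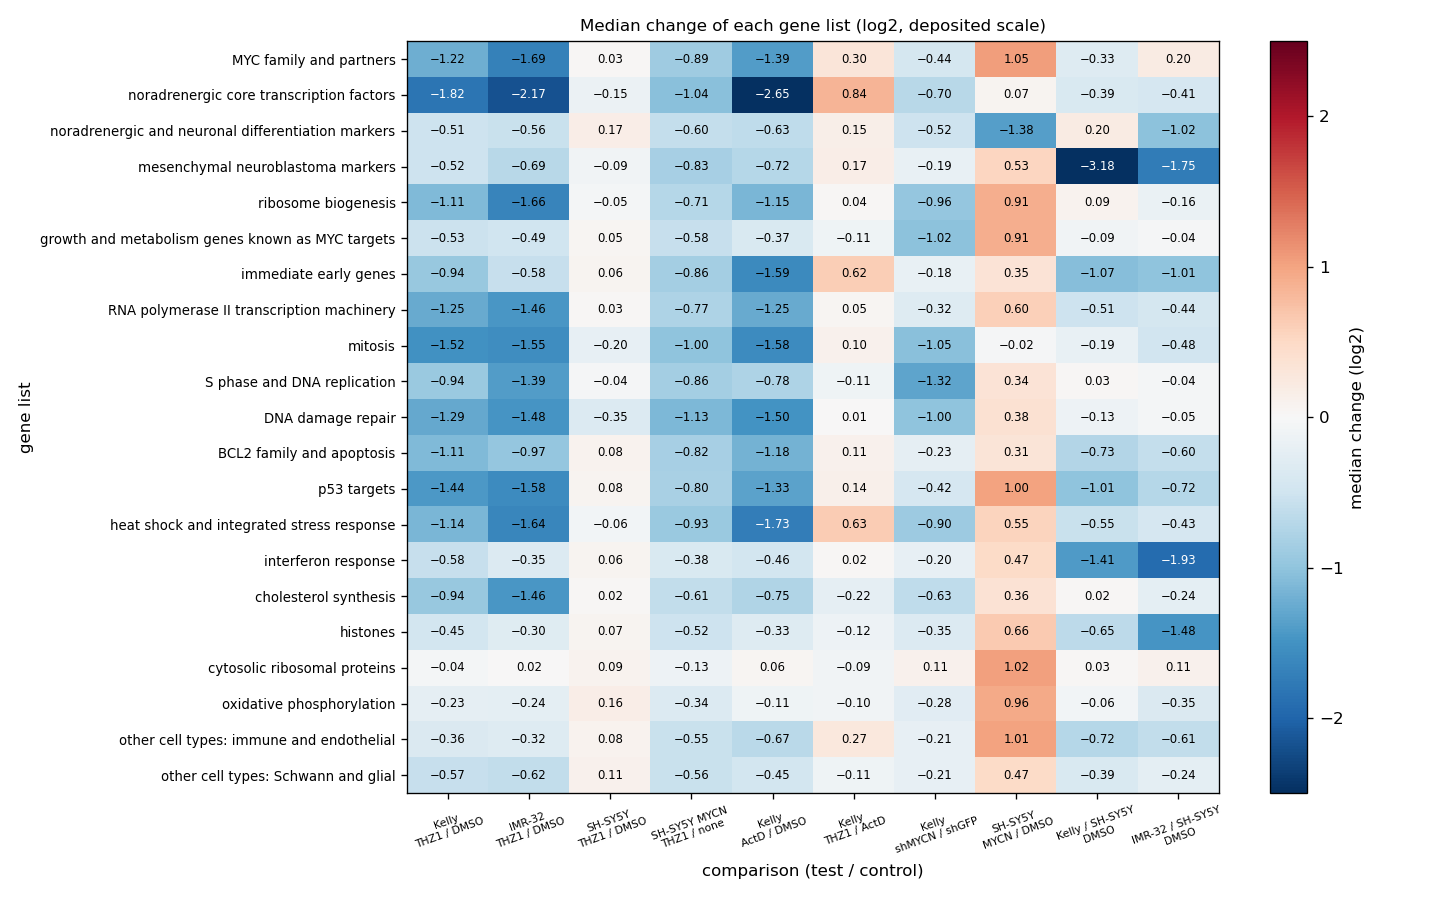
Median log2 change of each of 21 gene lists in 10 comparisons, as a colour with its value. The core transcription factors reach −1.82 in Kelly and −2.17 in IMR-32 with THZ1.

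The changes over 11666 genes were compared between comparisons by 8 correlations across genes, which are not independent replicates. Kelly and IMR-32 responded to THZ1 with a Pearson r of 0.853, with 9527 genes lower in both where 8897 would be by chance from the counts. Once array medians were equal, 2091 were lower in both (648 by chance) and 6001 higher in both (4038 by chance). The SH-SY5Y response correlated with that of Kelly at 0.538, of IMR-32 at 0.528 and of SH-SY5Y with MYCN at 0.792. THZ1 and actinomycin D in Kelly gave 0.840, but they share the DMSO arrays. Sharing alone gave 0.447 in simulated data with no effect, with a covariance of 0.0122 against 0.483 observed. In both 9141 genes were lower (1946 lower and 6188 higher at equal array medians), with no count for chance, since the shared arrays tie the calls. Knockdown of MYCN in Kelly correlated with THZ1 at 0.0426 (0.123 without the filter on level) and with MYCN in SH-SY5Y at 0.0369. THZ1 and MYCN in SH-SY5Y share the DMSO arrays and gave 0.0454 (0.146 without the filter), with a covariance of 0.00865 where sharing alone gave 0.0122.

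**Figure D4:**
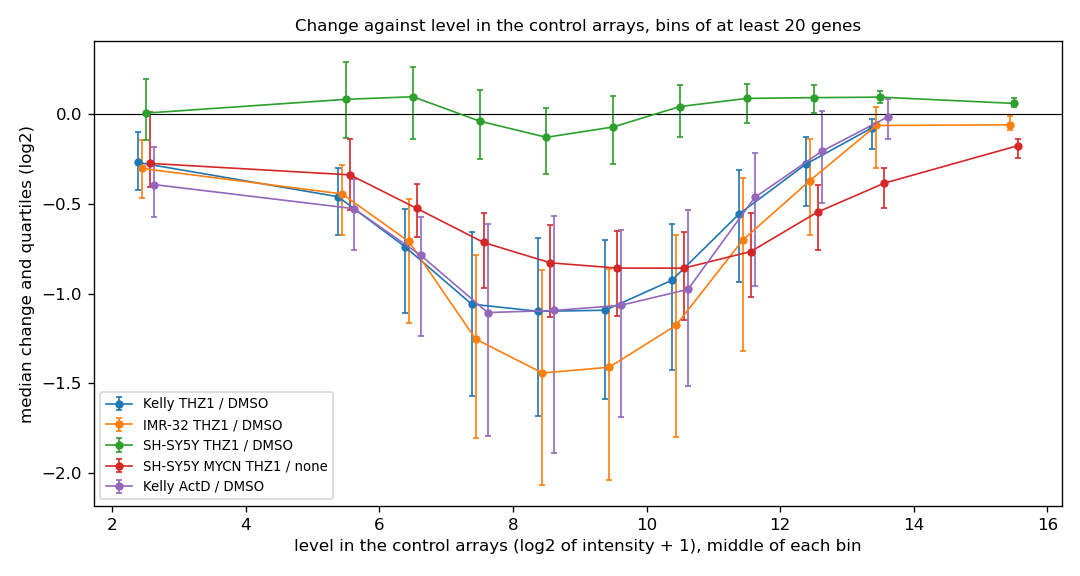
Median log2 change by log2 level in the control group, for 5 drug comparisons. Over all levels the median was −0.81 in Kelly and −1.002 in IMR-32 with THZ1.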

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

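The tests of matched level, of the common offset per array and of the levels in SH-SY5Y with MYCN were chosen only after the result was seen, and those of other splits and of a response like that of Kelly were chosen before.

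A difference between groups, tested as such, marked 3 results: the THZ1 effect differed from that in SH-SY5Y for 9531 genes in Kelly, 9860 in IMR-32 and 9775 in SH-SY5Y with MYCN. The line labels were permuted within THZ1 and within DMSO after removing the mean of each line. For Kelly 1 of 100 splits, the real one, gave as many genes (highest other 8325), and for IMR-32 1 of 100 (highest other 6941). This is the smallest share that 100 splits can give. A random split of these arrays thus rarely gives as many, but their spread may be technical, so chance between cultures is not excluded. The high counts of other splits point to a structure of the arrays: the mixed groups keep part of the effects of both lines. For the counts of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05. There 1 split, the real one, gave as many genes as found in Kelly with THZ1 (10163, highest other 0), IMR-32 with THZ1 (10303, highest other 0), SH-SY5Y with THZ1 (1774, highest other 1), Kelly against SH-SY5Y (8702, highest other 0) and IMR-32 against SH-SY5Y (8578, highest other 0).

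The THZ1 effect in SH-SY5Y with MYCN differed from that in SH-SY5Y by nearly the same amount for most genes. With the array medians set equal 240 genes were called instead of 9775, so a common offset per array may account for most of the count, whether it came from RNA per cell or from the handling of the spike-in. The Kelly changes correlated with those of SH-SY5Y with MYCN at 0.642 and with those of SH-SY5Y at 0.538, a difference of 0.103, just past the 0.1 set beforehand, so MYCN may bring a response of the kind seen in Kelly. The IMR-32 changes correlated at 0.597 and 0.528, a difference of 0.0689, which is under it. The smaller changes in SH-SY5Y may lower a correlation through noise alone, which was not tested. All arrays with added MYCN form a set of their own, and those without THZ1 have no vehicle in the labels. Both explanations therefore stay open.

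Data outside the main measurement marked 2 results: MYCN probe sets that do not represent the gene in the tests rose in SH-SY5Y with MYCN against SH-SY5Y with DMSO, B by 3.84 and C by 2.47, while the brightest probe set fell. In the same comparison most called genes were higher, and the background probe sets were higher by 0.789, so a difference between sets of arrays cannot be told apart from an effect of MYCN for the genes that rose, since all arrays with added MYCN belong to 1 set. The noradrenergic and neuronal markers had a median change of −1.38, which excludes a common upward offset as the cause for these genes, and an effect of MYCN or of the selection of cells may explain it, untested.

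The third pattern was that bright genes such as the cytosolic ribosomal proteins changed least after THZ1 and actinomycin D in Kelly and IMR-32, a list whose changes turn positive with equal array medians. The brightest probe set with DMSO in Kelly lay 0.736 above the ribosomal median, with 79 probe sets above that median, so this leaves an upper limit of the signal undecided. In SH-SY5Y with MYCN the ribosomal median (14.69) lay above the brightest probe set in Kelly (14.47), which argues against a limit at that level there, but the brightest probe set was higher too (15.61) and those arrays form a set of their own. Other genes within 0.1 log2 of a ribosomal protein's level changed by −0.218 (188 genes), against −0.81 for all genes, so a loss of response at high brightness for any gene may explain part of the pattern. Against it, 18 of the 188 fell by at least the median of all genes, HAND2 fell by 2.81 from 13.05 and MYCN probe set D by 1.98 from 13.56, and genes matched likewise rose by 0.667 in SH-SY5Y with MYCN against DMSO, where all rose by 0.445. Large falls show even where small ones are hidden, and that rise is between sets of arrays, so this stays open. Long-lived transcripts, which would be bright and change little within 6 h, stay open and were not tested.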

How the results depend on the processing

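Scaling to the bright ERCC probe sets, equal median differences of the arrays from their mean (for counts, genes and list tests), the lists of matched brightness, and averaged probe sets for the genes shared by the THZ1 comparisons were chosen only after the data were seen.

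Of the 13 counts of called genes all stayed within 1.5 times their value when the bright or the median ERCC probe sets were set equal, with the mean of all probe sets, a pseudocount of 32 and replicate numbers as blocks. The bright ERCC probe sets were already at about the same level on every array, so setting them equal could change little. At least 2-fold changes, a stricter threshold by construction, left 4615 genes in Kelly with THZ1, 5862 in IMR-32, 174 in SH-SY5Y, 3131 in SH-SY5Y with MYCN, 4789 for actinomycin D, 606 for THZ1 against it, 2104 for shMYCN, 1460 for MYCN in SH-SY5Y, 3576 and 3279 for Kelly and IMR-32 against SH-SY5Y, and 4347, 5691 and 1597 for the differences of effects (Kelly, IMR-32, SH-SY5Y with MYCN). Equal array medians, which take out a shift shared by all genes, gave 5484 genes in SH-SY5Y with THZ1, 5103 in SH-SY5Y with MYCN, 5126 for THZ1 against actinomycin D, and 6337 (Kelly) and 240 (SH-SY5Y with MYCN) for differences. With equal median differences these 5 were 3882, 4264, 4548, 5443 and 362. Fits on the compared groups alone gave 2666 in SH-SY5Y with THZ1 and 3558 for shMYCN, where the cause was not tested. No filter gave 13182 of 18244 genes for MYCN in SH-SY5Y, against 7567 of 11666 in the main fit. In that comparison the background probe sets were 0.79 higher, and tested genes with a control level up to 5 had a median rise of 0.75. For such faint genes a difference between sets of arrays cannot be told apart from an effect of MYCN.

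Leaving out 1 array gave 9488 to 10517 in Kelly, 9496 to 10508 in IMR-32, 1232 to 1682 in SH-SY5Y and 8731 to 9465 in SH-SY5Y with MYCN, and 1604 to 2341 for THZ1 against actinomycin D, the lowest without Kelly actinomycin D replicate 1. A lone array left in a group was assumed to vary like those of the other groups. The median change was −0.77 to −0.73 in SH-SY5Y with MYCN, the correlation of Kelly with IMR-32 0.843 to 0.855. Replicate numbers as blocks gave counts of 0.935 to 1.03 times the main ones, and same-numbered arrays deviated from their groups with r of −0.163 to 0.111, so the numbers were not taken to pair arrays.

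With equal array medians, which took out more than the median change, the medians turned to 0.38 in Kelly, 0.43 in IMR-32, 0.15 in SH-SY5Y with MYCN and 0.50 with actinomycin D. They kept their direction in the settings that follow. With no filter they were −0.52, −0.58, −0.55 and −0.54, and 0.57 for MYCN in SH-SY5Y; the cause was not tested. A pseudocount of 32, which damps faint genes, gave −0.66, −0.80, −0.66 and −0.64. With the median ERCC probe set equal they were −1.21 in IMR-32, −0.68 in SH-SY5Y with MYCN, −1.05 for actinomycin D, 0.14 for THZ1 against it and 0.37 for MYCN in SH-SY5Y; the cause was not tested. The mean of all probe sets gave −0.81 in IMR-32 and −0.62 in SH-SY5Y with MYCN. With no filter the correlations were 0.870 (Kelly and IMR-32), 0.491 (Kelly and SH-SY5Y), 0.491 (IMR-32 and SH-SY5Y), 0.645 (SH-SY5Y without and with MYCN), 0.123 (Kelly THZ1 and shMYCN), 0.870 (THZ1 and actinomycin D) and 0.146 (THZ1 and MYCN in SH-SY5Y). Of 273 list tests 92 were called, none with an estimated correlation (adjusted p 0.314 to 0.987, 4 at an unadjusted p under 0.05), 3 with equal median differences as well (the immediate early genes for THZ1 against actinomycin D, the noradrenergic and neuronal markers for MYCN in SH-SY5Y and the mesenchymal markers for Kelly against SH-SY5Y), and 99 with the median ERCC probe set equal, and fry called 196.

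Of 322 named gene results the direction turned as follows, called ones given first. With equal array medians, by construction of the shift, MYC in Kelly with THZ1 was 0.62, NEFL 0.011, SDHA 0.34, IRF9 in IMR-32 0.31, MYCN in SH-SY5Y with MYCN and THZ1 0.20, MYC with actinomycin D 0.44 and CDK7 in the difference for SH-SY5Y with MYCN 0.0046. MYC was 1.34 in IMR-32, 0.70 in the Kelly difference and 0.37 with shMYCN, MYCN 0.13 in SH-SY5Y with THZ1 and CDK7 0.040 with shMYCN. With equal median differences, MYC was 0.33 in Kelly and 0.050 with actinomycin D, SDHA 0.052, and MYCN 0.076 in SH-SY5Y with MYCN and THZ1. Among uncalled results, MYC was 0.97 in IMR-32, 0.52 in the Kelly difference and 0.27 with shMYCN, and MYCN 0.018 in SH-SY5Y with THZ1. The mean of all probe sets, which differ in what they read, gave MYCN 1.03 in SH-SY5Y with MYCN, KMT5B −0.43, DMXL1 −0.16 and RPS25 −0.36. It gave 0.17 for the uncalled MYCN with THZ1 in SH-SY5Y. For MYC, all near 0, a pseudocount of 32 gave 0.056 in the Kelly difference and 8.6e-04 with shMYCN, and the median ERCC probe set −0.057 in the IMR-32 difference. Leaving out 1 array, MYC ranged from −0.26 to 0.027 in IMR-32, −0.024 to 0.27 in its difference and −0.30 to 0.28 with shMYCN, and MYCN from −0.14 to 0.049 in SH-SY5Y with THZ1. Among results that kept their direction, calls ended for 9 with equal array medians and 6 with equal median differences. Calls ended for 7 with the mean of all probe sets (among them DPY19L3, PHF12, DMXL1 and ATM) and 4 with the median ERCC probe set (among them RPL7). They ended for 1 with a pseudocount of 32 (MYC in Kelly) and 9 of 1989 when 1 array was left out. Some results that turned, such as CDK7 in the difference for SH-SY5Y with MYCN at equal array medians, lost their call as well. In SH-SY5Y, NEFM lost its call without THZ1 replicate 1 (0.53) or 3 (0.50) or DMSO replicate 1 (0.50) or 3 (0.53), and CHGB without THZ1 replicate 1 (0.47) or 2 (0.44) or DMSO replicate 1 (0.41). In IMR-32, RPL7 did without DMSO replicate 1 (0.30) or THZ1 replicate 2 (0.34). The cause was not tested. Signal over background limits the falls that can be measured, most of all in Kelly with shGFP and shMYCN, whose genes had the lowest median intensities.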

Other observations

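The small nucleolar RNAs, the histone class and the genes shared by the THZ1 comparisons were picked after their values were seen, while the test of the zinc finger genes was chosen before.

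Small nucleolar RNAs guide the modification of ribosomal RNA and are cut from introns of other genes. Their probe sets, counted here together with those of Cajal body RNAs, stood out among the few that rose in Kelly and IMR-32. Whether these probe sets read the mature RNAs or the longer transcripts was not tested. Of 35 tested, 11 rose and 15 fell with THZ1 in Kelly, but 30 were higher and 1 lower with equal array medians. In IMR-32 10 rose and 16 fell (34 higher and 0 lower with equal array medians), in SH-SY5Y 4 rose and 1 fell (17 and 1), in SH-SY5Y with MYCN 3 rose and 17 fell (22 and 3), and with actinomycin D 10 rose and 17 fell (30 and 0). Of 23 genes of replication-dependent histones, 6 rose and 6 fell with THZ1 in Kelly (21 higher and 0 lower with equal array medians), 7 rose and 4 fell in IMR-32 (23 and 0), and 5 rose and 0 fell in SH-SY5Y (12 and 0). In SH-SY5Y with MYCN 0 rose and 15 fell (15 and 0), with actinomycin D 1 rose and 14 fell (18 and 1), and 10 were higher and 0 lower with THZ1 than with actinomycin D (8 and 6). Histone probe sets can read near-identical family members, so the members are not separate measurements.

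Across the 4 comparisons of THZ1 with its control, which share no arrays, 1367 genes were lower in all 4, where independent calls would give 973. Among them were PPP1R10, ZC3H4, which ends the synthesis of unstable transcripts (−3.40 ± 0.16 in Kelly, −4.34 ± 0.16 in IMR-32, −1.48 ± 0.16 in SH-SY5Y and −2.67 ± 0.19 in SH-SY5Y with MYCN), and INTS6, a part of the complex that attenuates RNA polymerase II (−3.21 ± 0.16, −3.58 ± 0.16, −1.53 ± 0.16 and −2.25 ± 0.19). With averaged probe sets both stayed lower in all 4, by less (ZC3H4 −2.22, −3.08, −0.91 and −2.06; INTS6 −1.16, −1.27, −0.45 and −0.65). Only 6 genes were higher in all 4 (9.43e-06 for independent calls): DPY19L3, EID3, PRKAA1, SNHG17, SNORA2A and SNORA65. When all probe sets of a gene were averaged, 948 of the 1367 stayed lower in all 4 and 4 of the 6 higher, while DPY19L3 and PRKAA1 were higher in SH-SY5Y alone. EID3 rose by 0.96 ± 0.14, 1.36 ± 0.14, 1.02 ± 0.14 and 1.30 ± 0.17, and PRKAA1, a subunit of an energy sensor kinase, by 0.94 ± 0.14, 0.46 ± 0.14, 0.82 ± 0.14 and 0.58 ± 0.17, while both fell with actinomycin D (−1.54 ± 0.15 and −0.57 ± 0.16). PHF12 rose in 3 of the 4 and fell in IMR-32 (−0.28 ± 0.13), but with averaged probe sets it fell in Kelly too (−0.31) and rose in SH-SY5Y alone. Genes are not independent replicates.

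The hypothesis was tested that genes of zinc finger transcription factors (337 genes with symbols ZNF or ZFP) fall more than other genes of the same brightness. Their median was −1.50 in Kelly with THZ1, −1.64 in IMR-32, −0.24 in SH-SY5Y, −0.9999 in SH-SY5Y with MYCN and −1.77 with actinomycin D, with 326, 327, 101, 321 and 321 genes lower, and with equal array medians 179, 165, 96, 96 and 186 lower and 87, 99, 37, 42 and 82 higher. Against the median of 10000 random lists of the same brightness the class lay at −0.704, −0.632, −0.223, −0.271 and −0.944. It lay below every random list in each comparison. The share of lists as low was 1e-04, the smallest these lists can give. Such a share treats genes as independent units and takes no account of the spread between arrays. Short-lived transcripts may explain the larger fall of the class, since actinomycin D gave the largest gap, but half-lives were not measured.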
